A study of Homo sapiens with 24 samples.

How the data were processed

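Total RNA of 24 cultures was made into poly(A)-selected, stranded libraries and read as pairs of 75 bases. The cultures were Rh30 and RD cells under 4 treatments for 5 days, with 3 replicates in each of 8 groups. The dose of SGI-110 was 0.5 µM. The submitters' processing notes list Trim Galore 0.4.2, HISAT2 2.1.0, featureCounts 1.5.1, DESeq2 1.16.1 and DESeq with the GRCh38 build, without roles or order. The model formula, the cell line each comparison refers to and the filters are not given in the sources used here.

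The files hold 4 comparison tables of 29639 genes: SGI-110, dasatinib and the combination against DMSO, and the combination against SGI-110. The signal of each gene is baseMean, deposited by the authors and read here, from the column names, as DESeq2's mean count over libraries after division by size factors. It is identical in the 4 tables. The deposited lfcSE column is the standard error of the log2 fold change. The deposited stat column is a score, the Wald statistic of each gene. The p-value and the Benjamini-Hochberg adjusted value come from the same Wald test, as the authors computed them, and the adjusted value is missing for genes under a level that differs between tables. A log2 fold change was obtained as the product of the Wald statistic and its standard error. Combination against DMSO minus SGI-110 against DMSO matched combination against SGI-110 to within 0.00152 log2, with a median gap of 8.09e-07. These 3 comparisons can therefore be read as contrasts of 1 fit. Dasatinib against DMSO is in no such sum, and that it comes from the same fit is an assumption, on which the interaction and the combination against dasatinib rest. No value per library was used, so depth per sample is unknown, and precision rests on the deposited standard errors.

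The comparisons had been planned as joined over both cell lines. The deposited standard errors have the size expected of 3 libraries per treatment: the largest was 6.01, against 6.01 for 3 libraries and 4.25 for 6 in a fit of 24 libraries with the highest dispersion. Fold changes are therefore read as those of 1 cell line, which the tables leave unnamed, and the mean normalised count as that of all 24 libraries. A treatment was called unmeasurable for a gene when the standard error of that group was at least 1.17 log2. This is the value for 3 libraries at a fitted level of 0.5 counts per library. The call was made for 7945 genes in DMSO, 4166 with SGI-110, 8050 with dasatinib and 4586 with the combination. A large spread between libraries can give the same standard error at a higher level, so such a group need not lack the transcript. No fold change of or against such a group is given, and list medians and means cover the members measured in both groups, or in all treatments for the interaction.

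Genes were counted as past the threshold at a deposited adjusted p under 0.05. The interaction (combination against SGI-110 minus dasatinib against DMSO) and the combination against dasatinib were computed from the deposited values. The variance of each group was solved from the deposited standard errors, groups were taken as independent, and a two-sided Wald p was adjusted by Benjamini-Hochberg over all 29639 genes. For 1 gene a group variance came out negative. On simulated data with 200 changed genes, this test found 63.5%, 94.5% and 98.5% of interactions of 0.5, 1 and 2 log2, and 4.51% to 6.19% of the calls were false. For the combination against dasatinib it found 87%, 98% and 99.5%, and 4.39% to 6.13% of the calls were false. The changed genes all had a mean normalised count of at least 100 and an interaction standard error under 1 log2. Genes at lower levels were not covered. The noise was drawn from the same solved variances that the test uses, so the share of false calls does not check those variances or the single fit.

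Before the data were examined, 42 gene lists were fixed for pathways, complexes, the muscle lineage and other cell types. Each was tested with limma 3.58.1 (cameraPR, R 4.3.3) on the Wald statistic, with an inter-gene correlation of 0.01, Benjamini-Hochberg over the lists of a comparison and a minimum of 5 members. The test compares the members of a list with all other genes. Its direction is relative to those genes, so a list can fail although many members moved. An estimated correlation needs values per library, so 0.05 was tried in its place. On simulated data the test found a list shifted by 1 standard deviation in 18 of 20 draws and called 1 of 820 unshifted lists. The simulated genes were independent of each other. The rate of false calls for lists whose members move together was therefore not measured. Each list also has its members counted over all genes and adjusted over the list alone. Counts are of the members found in the tables, which for replication histones are 13 of 26; the libraries are poly(A)-selected, and most of these transcripts lack a poly(A) tail.

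Genes named in the text follow a rule fixed before the data were examined. It takes the 8 largest rises and falls among genes past the threshold with a mean normalised count of at least 100 and a protein-type symbol, the 4 members with the smallest adjusted p of each list past the threshold, and 32 fixed genes. The largest rises and falls among genes measured in both groups were added after seeing the data. Further members named beside a list, such as USP18, were chosen after seeing their values. Symbols were matched to GENCODE 29: 21527 matched once, 70 more than once and 8042 not at all. Of the gene names 27 read as dates, and 4 entries share a name with another. Overlaps of calls were set beside the product of the counts, and covariances of log2 changes beside 100 simulated draws of unchanged groups with shared controls. For genes chosen by SGI-110 and read in the combination against SGI-110, the 100 draws kept shrunken SGI-110 effects and no effect of dasatinib, with the p limits of the deposited calls; this was added after seeing the data.

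The alternatives were a stricter adjusted p of 0.01, Bonferroni, a log2 change of at least 1, a mean normalised count of at least 50, adjustment over every gene with a p-value, centring on the median gene, other list settings and leaving out genes with an unmeasurable group. Random lists were drawn 10000 times from the 100 nearest genes of each member. Values were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9. The difference between the cell lines was planned and is not analysed here, since no deposited comparison gives it.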

Results

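Messenger RNA was sequenced in Rh30, an alveolar rhabdomyosarcoma cell line, and in RD, an embryonal rhabdomyosarcoma cell line. Rhabdomyosarcoma is a tumour of the skeletal muscle lineage. Cells of each line were kept for 5 days with the solvent DMSO, with SGI-110 at 0.5 µM, with dasatinib, or with both drugs. SGI-110 (guadecitabine) releases decitabine, which is built into DNA and blocks DNA methyltransferases, and dasatinib inhibits kinases of the SRC and ABL families. Each of the 8 groups had 3 libraries, 24 in all. The values used here come from 4 tables of the authors' own comparisons, which cover 29639 genes each and hold no value per library. The total count of each library is therefore unknown, no counting interval can be given, and how many replicates share a direction cannot be shown. The mean normalised count per gene had a median of 24.5 and a maximum of 324220 in the authors' deposited table. The tables name no cell line, and their standard errors have the size expected of 3 libraries per treatment from 1 line, so each fold change below is read as the response of 1 line that the tables leave unnamed. Values are log2 fold changes with the deposited standard error after the ± sign. The fold changes were computed here from the deposited Wald statistic and standard error. List counts, list medians and list test adjusted p were also computed here. For these, the words "the authors' deposited table" name only the source of the gene values. The adjusted p of single genes in the 4 deposited comparisons are the authors' own. A gene is described as having no measurable level in a treatment when that group's standard error was at least 1.17 log2. Such a value is reached at 0.5 counts per library, and a large spread between libraries can also give it. No fold change against such a treatment is given.

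The first comparison asks what SGI-110 alone did. Genes of germ cells and cancer-testis genes, which are normally silent outside the germ line, rose almost without exception: 24 of 24 germline and meiosis genes and 27 of 30 cancer-testis genes were higher than in DMSO in the authors' deposited table. Interferon-stimulated genes, replication histone genes, collagen and matrix genes, and target genes of the YAP and TAZ coactivators also rose. All 30 ribosomal protein genes tested were lower, as were 18 of 20 genes of the ATF4 stress response, 13 of 14 endoplasmic reticulum chaperone genes and 22 of 30 DNA replication genes. In total 8671 genes rose and 4866 fell at an adjusted p under 0.05, out of 28489 with an adjusted p, in the authors' deposited table.

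Among single genes, DAZL, an RNA-binding protein of germ cells (GRCh38, chromosome 3, 16586792 to 16670306), had no measurable level in DMSO and rose with SGI-110, with an adjusted p of 7.1e-30 in the authors' deposited table. TKTL1, SSX1, PNMA5, TEX13C, GDPD4 and KHNYN likewise had no measurable level in DMSO, with adjusted p from 6.1e-29 (TKTL1) to 8.9e-24 (KHNYN) in the authors' deposited table. The largest rises among genes measured in both groups, a choice made after seeing the data, included the imprinted gene NNAT (12.01 ± 0.72) and DNAH3 (10.65 ± 0.84) in the authors' deposited table. HSPA2, a heat shock protein gene, rose by 10.46 ± 0.84 and ERVW-1 by 10.30 ± 0.46 in the authors' deposited table. The standard errors of these 4 genes lie above the median of 0.0846 for genes with a mean normalised count of at least 100. Their DMSO levels may lie close to the limit of measurement, so the sizes of these rises are uncertain. The largest falls were those of BEST1 (-3.66 ± 0.22), KLHDC7B (-3.00 ± 0.33), SGCD (-2.59 ± 0.13), which encodes delta-sarcoglycan of the muscle membrane, and KCNT1 (-2.54 ± 0.19) in the authors' deposited table. LONP1, a mitochondrial protease, fell by 2.45 on the log2 scale and INHBE fell by 2.34 in the authors' deposited table.

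List tests were repeated with an inter-gene correlation of 0.05 in place of 0.01, on ranks, at a mean count of at least 50 and without genes that had no measurable level in a treatment. Where any of these 4 settings ended a call, the highest adjusted p among them follows the call as "up to". A setting that left a list under 5 members was not run, as happened for cancer-testis, endothelial and epithelial lists. For these, a missing "up to" covers only the settings that were run. The log2 fold change as the statistic is not part of "up to". The cancer-testis list passed the list test (limma, adjusted p = 3.96e-09) with 27 members higher, none lower and 3 not past the threshold, from the authors' deposited table. PRAME, MAGEA4, MAGEC1 and MAGEC2 had no measurable level in DMSO, and their adjusted p were 2.1e-21, 1.2e-16, 2.3e-22 and 2.3e-22 in the authors' deposited table. In the germline list (adjusted p = 1.93e-28), the piRNA pathway genes TDRD1 (3.92 ± 0.10) and PIWIL2 (3.90 ± 0.13) rose, as did TEX14 (2.87 ± 0.11) and TEX11 (7.21 ± 0.34), in the authors' deposited table. Of the imprinted genes 14 of 22 rose and 6 fell (adjusted p = 0.00096), and 15 rose when adjusted over the list alone, from the authors' deposited table. INPP5F stood at 1.59 ± 0.06, PEG10 at 0.80 ± 0.05 and MEG3 at 1.87 ± 0.13 in the authors' deposited table. Replication histones rose in 10 of the 13 members found in the tables, of 26 listed (adjusted p = 1.93e-28), with the linker histone gene HIST1H1C at 5.74 ± 0.11 and HIST1H2BK at 4.93 ± 0.12 in the authors' deposited table. Because the libraries are poly(A)-selected, histone values in every comparison mainly reflect transcripts with a poly(A) tail. Whether total histone transcripts changed was not measured. For the cancer-testis, germline and histone lists the counts adjusted over the list alone were the same.

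Interferon-stimulated genes rose in 27 of 32 members and fell in 1, with a median of 1.56 log2 over the 27 members measured in both groups and a list test adjusted p of 3.8e-10, from the authors' deposited table. The ubiquitin-like modifier ISG15 (chromosome 1, 1001138 to 1014540) rose 4.82-fold (2.27 ± 0.10, adjusted p = 3.1e-119) in the authors' deposited table. IFI44 (1.44 ± 0.06), IFIT2 (2.46 ± 0.14), IFI6 (2.12 ± 0.13) and IFIT1 (1.87 ± 0.17) also rose in the authors' deposited table. USP18, a brake on interferon receptor signalling, was the member that fell (-0.66 ± 0.13) in the authors' deposited table. The antigen presentation list moved the same way (14 of 20 higher, 1 lower, adjusted p = 0.00361), from the authors' deposited table. HLA-E stood at 1.06 ± 0.06, HLA-B at 0.52 ± 0.08 and TAP2, the 1 member that fell, at -0.65 ± 0.08 in the authors' deposited table. Inflammatory NF-kB genes rose in 15 of 20 members (adjusted p = 0.000519), for example IL11 (1.14 ± 0.08) and the chemokine gene CCL2 (2.36 ± 0.30), in the authors' deposited table. By counts adjusted over the list alone, 17 of these 20 rose, and the interferon and antigen presentation counts were unchanged. Nucleic acid sensors had 8 of 12 members higher and 1 lower, and the list test was not past the threshold (adjusted p = 0.0604), from the authors' deposited table; adjusted over the list alone, 2 were lower.

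Matrix and cytoskeleton genes formed another large block of rises. Collagen and matrix genes rose in 23 of 30 members and fell in 5 (list test, limma, adjusted p = 2.36e-25), computed from the authors' deposited table. The type I collagen gene COL1A1 stood at 4.50 ± 0.07, TGFBI at 4.52 ± 0.11 and THBS1 at 3.59 ± 0.07 in the authors' deposited table. Targets of YAP and TAZ rose in 22 of 24 members and fell in 1 (adjusted p = 1.37e-18): CTGF rose 27.3-fold (4.77 ± 0.20) and CYR61 (chromosome 1, 85580761 to 85583962) by 2.43 ± 0.06 in the authors' deposited table. TGF-beta targets rose in 14 of 15 members (adjusted p = 3.53e-17) and SRF and cytoskeleton genes in 17 of 22 with 1 lower (adjusted p = 1.43e-05), from the authors' deposited table. Focal adhesion and integrin genes rose in 12 of 22 and fell in 3, with a median of 0.16 (adjusted p = 0.0109, up to 0.0907), from the authors' deposited table. The integrin gene ITGA3 (2.61 ± 0.09), the smooth muscle gene TAGLN (2.01 ± 0.15) and LTBP2 (3.07 ± 0.14) were members that rose in the authors' deposited table. Markers of other cell types moved with this block: fibroblast markers rose in 10 of 14 members (adjusted p = 1.45e-10), endothelial in 8 of 11 (adjusted p = 0.000575) and epithelial in 11 of 14 (adjusted p = 0.00216), from the authors' deposited table. PECAM1 of endothelial cells rose by 1.67 ± 0.08 and CLDN4 of epithelia by 1.96 ± 0.13, and the keratin genes KRT8 and KRT18 had no measurable level in DMSO (adjusted p = 6.1e-14 and 1.8e-19) in the authors' deposited table. COL1A1 stands in both the matrix and the fibroblast list. Immune markers (8 of 17 higher, 1 lower, adjusted p = 0.221), neural markers (10 of 15 higher, 1 lower, 0.11) and adipocyte and liver markers (5 of 12 higher, 0.188) were not past the list threshold, from the authors' deposited table. Every count of this paragraph was the same when adjusted over the list alone.

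Growth and signalling genes also changed. Feedback genes of MAPK signalling rose in 14 of 20 members and fell in 2 (adjusted p = 6.35e-09) in the authors' deposited table. The G1 cyclin gene CCND1 stood at 2.12 ± 0.05, the receptor kinase gene EPHA2 at 2.37 ± 0.09 and SPRY2 at -0.91 ± 0.05 in the authors' deposited table. Immediate early AP-1 genes rose in 14 of 20 and fell in 1 (adjusted p = 5.92e-05), with NR4A3 (3.60 ± 0.17) and FOS (1.55 ± 0.11) among those that rose, in the authors' deposited table. Mitotic G2/M genes rose in 19 of 26 members and fell in 2 (adjusted p = 2.68e-08), including KIF20A (1.05 ± 0.05), AURKA (0.95 ± 0.06) and MKI67 (0.78 ± 0.05), in the authors' deposited table. Targets of p53 rose in 15 of 26 and fell in 4 (adjusted p = 0.00527), with PLK2 at 1.29 ± 0.05, DDB2 at 1.79 ± 0.11 and CDKN1A at 0.63 ± 0.08 in the authors' deposited table. Of the other kinases that dasatinib binds 13 of 18 rose and 1 fell (adjusted p = 0.00371), with PDGFRB at 1.02 ± 0.12 and DDR2 at -1.43 ± 0.07 in the authors' deposited table. Apoptosis regulators (12 of 20 higher, 3 lower, adjusted p = 0.0285, up to 0.107) and Notch targets (10 of 15 higher, 3 lower, 0.0175, up to 0.059) passed as well, with CFLAR at 1.19 ± 0.09 and HES1 at 2.00 ± 0.13 in the authors' deposited table. Adjusted over the list alone, 15 MAPK feedback genes, 20 G2/M genes, 16 p53 targets and 11 Notch targets rose, and the other counts were the same. With the log2 fold change as the statistic, the MAPK feedback, G2/M and p53 lists did not pass and pointed down. The AP-1 and other dasatinib kinase lists did not pass in that setting either.

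Genes of protein synthesis and folding, DNA replication and cholesterol synthesis fell. ATF4 (-1.48 ± 0.07) fell together with its target genes DDIT3 (-1.64 ± 0.07), DDIT4 (-1.50 ± 0.08) and PHGDH (-1.72 ± 0.08), the first enzyme of serine synthesis, in the authors' deposited table. The list had a median of -1.34 (adjusted p = 1.91e-25), from the authors' deposited table. HSPA5, the main chaperone of the endoplasmic reticulum, fell by 1.25 on the log2 scale and HERPUD1 by 1.56, in a list with a median of -0.67 (adjusted p = 5.37e-16), in the authors' deposited table. Ribosomal protein genes had a median of -0.54 (adjusted p = 6.35e-17), with RPL22 at -1.33 ± 0.07 and RPL11 at -0.99 ± 0.07 in the authors' deposited table. DNA replication genes had a median of -0.36 (adjusted p = 2e-07; 3 higher), with the polymerase gene POLA1 at -0.94 ± 0.06 and MCM3 at -0.55 ± 0.04 in the authors' deposited table. Cholesterol synthesis genes fell in 15 of 22 members and rose in 3 (adjusted p = 0.00307, up to 0.0664), with SREBF2 at -0.61 ± 0.07 and DHCR7 at -0.82 ± 0.09 in the authors' deposited table. Over the 21 members measured in both groups their median was -0.31 and their mean 0.0671, so the mean differs in sign from the test. Adjusted over the list alone, 4 replication genes rose and 16 cholesterol genes fell, and the counts of the other lists of this paragraph were the same.

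Muscle and tumour lineage genes split. Contractile genes rose in 18 of 30 members and fell in 7 (adjusted p = 0.0177, up to 0.118), with the titin gene TTN at 1.75 ± 0.08, MYL1 at 1.76 ± 0.11 and MYBPH at 3.11 ± 0.23 in the authors' deposited table. Myogenic regulators had 11 of 20 higher and 8 lower and their list was not past the threshold (adjusted p = 0.917), from the authors' deposited table. MYOG rose (0.46 ± 0.07) and MYOD1 stood at 0.21 ± 0.12 (adjusted p = 0.14) in the authors' deposited table. Targets of PAX3-FOXO1, the fusion protein of many alveolar tumours, fell in 11 of 19 members and rose in 6 (adjusted p = 1.32e-05, up to 0.0744), with a median of -0.25 and a mean of 0.19, from the authors' deposited table. Rh30 is alveolar and RD embryonal, so if the unnamed line were RD, these genes could not be read as targets of an expressed fusion protein. ABAT (-2.02 ± 0.08), the receptor kinase gene ALK (-1.99 ± 0.09) and PIPOX (-1.46 ± 0.08) fell and CNR1 rose (3.70 ± 0.20) in the authors' deposited table. FGFR4, a growth factor receptor gene of this lineage (chromosome 5, 177086886 to 177098144), fell by 1.31 on the log2 scale and PAX3 rose by 0.76 ± 0.08 in the authors' deposited table. The DNA methylation machinery fell in 9 of 15 members and rose in 4 (adjusted p = 0.033, up to 0.151), with a median of -0.23 and a mean of 0.13, from the authors' deposited table. DNMT1, the maintenance methyltransferase, fell (-0.32 ± 0.05), while DNMT3A (0.15 ± 0.04) and DNMT3B (1.63 ± 0.09) rose in the authors' deposited table. The counts of this paragraph were the same when adjusted over the list alone.

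The remaining lists were not past the list threshold for SGI-110. SRC family and ABL genes had 7 of 12 higher and none lower (adjusted p = 0.0718), and lysosome and autophagy genes 11 of 20 higher and 3 lower (0.0555), from the authors' deposited table. Hedgehog and Wnt genes had 10 of 19 higher and 5 lower (adjusted p = 0.156), from the authors' deposited table. Heat shock genes (6 of 11 higher, 3 lower, adjusted p = 0.418) and hypoxia and glycolysis genes (9 of 20 higher, 6 lower, 0.18) did not pass, from the authors' deposited table. Cell cycle inhibitors (4 of 10 higher, 3 lower, adjusted p = 0.716) and mitochondrial transcripts (3 of 13 higher, 3 lower, 0.168) did not pass either, from the authors' deposited table. With p adjusted over the list alone, 11 hedgehog and Wnt genes were higher and 4 cell cycle inhibitors lower, with the other counts the same. Of the 42 lists 30 passed, 23 higher and 7 lower. With the log2 fold change as the statistic 15 lists passed. Besides the lists named above for that setting, the matrix, YAP and TAZ, TGF-beta, SRF, NF-kB, antigen presentation and endothelial calls ended there. With an inter-gene correlation of 0.05 the calls of apoptosis regulators (adjusted p = 0.0958), contractile genes (0.0958), DNA methylation machinery (0.0955), focal adhesion (0.059) and Notch targets (0.059) were lost. Of the 8671 genes that rose 2646 had no measurable level in DMSO in the authors' deposited table, and among the 11759 genes with a mean normalised count of at least 100 the balance was 3833 higher and 4103 lower.

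**Figure D1:**
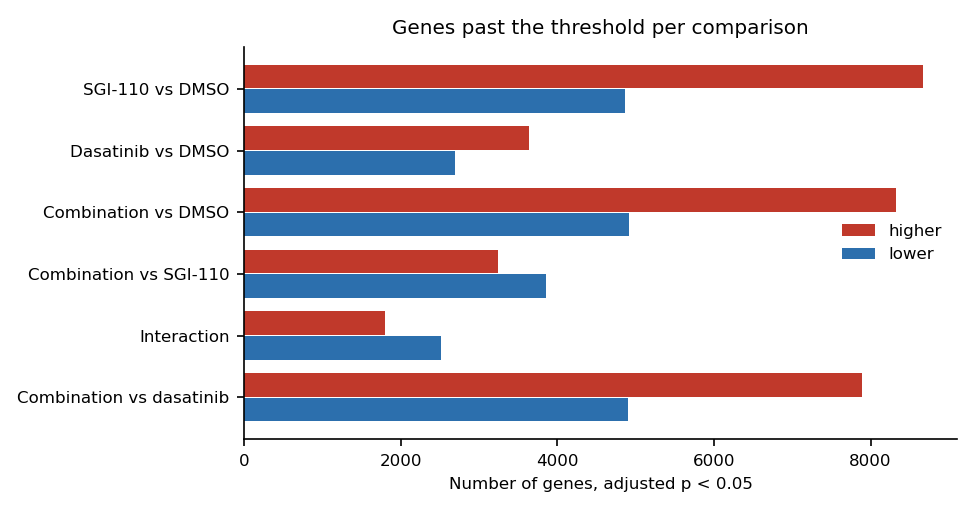
Number of genes past an adjusted p of 0.05 (horizontal axis, from 0) in each comparison, with genes that were higher in red and genes that were lower in blue, from the authors' deposited table and, for the interaction and the combination against dasatinib, computed from it. SGI-110 alone had 8671 genes higher and 4866 lower, and dasatinib alone 3636 higher and 2696 lower.

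The next comparison asks what dasatinib alone did. Mitotic genes rose without exception, 26 of 26, and 24 of 30 DNA replication genes rose in the authors' deposited table. Genes of muscle contraction (19 of 30, with 1 higher), antigen presentation (12 of 20) and endoplasmic reticulum chaperones (14 of 14) fell in the authors' deposited table. In total 3636 genes rose and 2696 fell out of 20445 with an adjusted p, and 423 rose and 598 fell by at least 1 log2, in the authors' deposited table. Centred on the median gene, a shift of 0.05 log2, 2889 rose and 3262 fell. Cancer-testis genes were not past the list threshold (1 of 30 higher, adjusted p = 0.868), and DAZL, PRAME and MAGEA4 had no measurable level with DMSO or with dasatinib in the authors' deposited table.

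The largest rise was that of AFAP1L2, an adaptor that binds SRC (4.35 ± 0.28, 20.4-fold), in the authors' deposited table. TXNIP, an inhibitor of thioredoxin and of glucose uptake (chromosome 1, 145992435 to 145996600), rose 11.1-fold (3.47 ± 0.10), and the phosphodiesterase gene PDE4B (3.17 ± 0.09) and OLFM1 (3.72 ± 0.75) rose in the authors' deposited table. LRFN5, EMILIN3, SSX1 and PCDH15 rose from no measurable level in DMSO, with adjusted p of 0.0074, 0.018, 0.028 and 0.046 in the authors' deposited table. The carboxypeptidase gene CPA4 (-3.21 ± 0.12), GPNMB (-3.21 ± 0.28), the myosin chaperone gene UNC45B (-2.98 ± 0.22) and WHRN (-2.89 ± 1.10) fell in the authors' deposited table. FAM9C, IAH1, EPB41L3 and COL6A3 fell to no measurable level, with adjusted p of 0.00033, 0.041, 0.041 and 0.041 in the authors' deposited table.

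G2/M genes had a median of 0.71 (list test, limma, adjusted p = 4.58e-80), from the authors' deposited table. HMMR stood at 1.21 ± 0.07, KIF20A at 0.98 ± 0.05, the kinase gene PLK1 at 0.95 ± 0.06 and MKI67 at 0.74 ± 0.05 in the authors' deposited table. DNA replication genes had a median of 0.29 (adjusted p = 1.08e-13), with CDC6 at 0.51 ± 0.05 and MCM6 at 0.63 ± 0.07 in the authors' deposited table. PAX3-FOXO1 targets rose in 12 of 19 members and fell in 3 (adjusted p = 4.38e-08), among them ASS1 (1.63 ± 0.07), NOS1 (0.72 ± 0.05) and ALK (0.67 ± 0.08), in the authors' deposited table. MAPK feedback genes rose in 12 of 20 and fell in 5 (adjusted p = 0.00069, up to 0.0698): ETV4 (1.37 ± 0.10) and the ERK phosphatase gene DUSP6 (0.87 ± 0.07) rose and MYC (-0.74 ± 0.06) fell in the authors' deposited table. Hedgehog and Wnt genes rose in 7 of 19 and fell in 1 (adjusted p = 0.00108), with HHIP at 0.86 ± 0.07 and PTCH1 at 0.68 ± 0.06 in the authors' deposited table. Imprinted genes rose in 6 of 22 and fell in 3 (adjusted p = 0.00108, up to 0.381), with PEG10 at 1.41 ± 0.05 in the authors' deposited table. Notch targets (6 of 15 higher, 2 lower, adjusted p = 0.0413, up to 0.239) and the DNA methylation machinery (6 of 15 higher, 1 lower, 0.0128, up to 0.158) passed, with HEYL at 1.04 ± 0.06 and DNMT3A at 0.65 ± 0.04 in the authors' deposited table. Adjusted over the list alone, 13 MAPK feedback, 8 hedgehog and Wnt, 7 Notch and 7 methylation genes rose and 4 PAX3-FOXO1 targets fell, and the other counts of this paragraph were the same.

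Contractile genes fell with a median of -0.60 (adjusted p = 1.76e-16) in the authors' deposited table. The troponin gene TNNT2 stood at -1.55 ± 0.07, the cardiac actin gene ACTC1 at -1.27 ± 0.08, TNNI1 at -1.30 ± 0.09 and MYL1 at -1.95 ± 0.19 in the authors' deposited table. Antigen presentation genes fell in 12 of 20 members and rose in none (adjusted p = 5.39e-12) in the authors' deposited table. HLA-B (chromosome 6, 31269491 to 31357188) fell to 0.365-fold (-1.45 ± 0.08), HLA-C stood at -0.98 ± 0.08 and the light chain gene B2M at -0.64 ± 0.06 in the authors' deposited table. Interferon-stimulated genes fell in 10 of 32 and rose in 2 (adjusted p = 0.0308, up to 0.184), with STAT2 at -0.62 ± 0.06 and ISG15 at -0.51 ± 0.12 in the authors' deposited table. Endoplasmic reticulum chaperones had a median of -0.58 (adjusted p = 1.75e-31), with HSPA5 at -1.34 ± 0.05 and HYOU1 at -1.09 ± 0.07 in the authors' deposited table. Ribosomal protein genes fell in 16 of 30 (adjusted p = 2.86e-05, median -0.19), lysosome and autophagy genes in 7 of 20 (0.000147) and focal adhesion and integrin genes in 7 of 22, with 3 higher (0.0018, up to 0.2), in the authors' deposited table. The sialidase gene NEU1 (-1.52 ± 0.10), the autophagy receptor gene SQSTM1 (-0.63 ± 0.07) and ITGA3 (-1.52 ± 0.12) fell in the authors' deposited table. With p adjusted over the list alone, 20 contractile, 20 ribosomal and 10 focal adhesion genes fell and 3 contractile and 4 focal adhesion genes rose, with the other counts the same.

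Of the kinase genes fixed in advance, FYN (0.61 ± 0.07), YES1 (0.39 ± 0.07), ABL1 (0.25 ± 0.06) and EPHA2 (0.38 ± 0.11) rose and PDGFRB fell (-0.94 ± 0.15) in the authors' deposited table. SRC stood at 0.07 ± 0.08 (adjusted p = 0.6) in the authors' deposited table. As a list, SRC family and ABL genes were not past the threshold (3 of 12 higher, 1 lower, adjusted p = 0.342), from the authors' deposited table. Neither were YAP and TAZ targets (4 of 24 higher, 8 lower, adjusted p = 0.0602) nor fibroblast markers (2 of 14 higher, 1 lower, 0.972), from the authors' deposited table. When adjusted over the list alone, 2 fibroblast markers were lower and no cancer-testis gene was higher. Of 42 lists 15 passed, 8 higher and 7 lower, and the interferon (adjusted p = 0.184), Notch (0.137) and DNA methylation machinery (0.0591) calls were lost with an inter-gene correlation of 0.05. With the log2 fold change in place of the Wald statistic, 1 list passed.

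The comparison of the combination with DMSO asks what both drugs did together. Germline genes (24 of 24) and cancer-testis genes (27 of 30) rose, together with histones, matrix genes and mitotic genes (25 of 26), in the authors' deposited table. Cholesterol synthesis genes fell in 18 of 22 members and rose in 3, with a median of -0.76 and a mean of -0.38 over the 21 measured in both groups, in the authors' deposited table. Interferon genes rose in 21 of 32 members and fell in 4, with a median of 0.38 over the 27 measured in both groups, in the authors' deposited table. Set against all other genes, their list was not past the threshold (limma, adjusted p = 0.155). In total 8326 genes rose and 4915 fell out of 27915 with an adjusted p in the authors' deposited table. At a mean normalised count of at least 100 the balance was 4042 higher and 3974 lower.

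DAZL, TEX13C, SSX1 and TKTL1 rose from no measurable level in DMSO, with adjusted p from 4.6e-28 (DAZL) to 4e-25 (TKTL1) in the authors' deposited table. NNAT (11.97 ± 0.72) and ERVW-1 (10.82 ± 0.46) rose from a DMSO level that counted as measured, in the authors' deposited table. As with SGI-110 alone, that level may lie close to the limit of measurement, so the sizes are uncertain. The largest falls were those of UNC45B (-3.53 ± 0.26), KCNT1 (-3.49 ± 0.20), TXLNB (-3.39 ± 0.26), BEST1 (-3.36 ± 0.22), the metalloprotease gene ADAMTS6 (-3.09 ± 0.10) and SGCD (-3.02 ± 0.14) in the authors' deposited table.

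Contractile genes went both ways, 11 of 30 higher and 12 lower, with TNNI1 at -2.71 ± 0.09, TNNT2 at -2.14 ± 0.07 and TTN at 1.00 ± 0.08 in the authors' deposited table. Their list test pointed down (limma, adjusted p = 0.00606, up to 0.535). Over the 27 members measured in both groups their median was -0.05 and their mean 0.12, so the mean differs in sign from the test. Cholesterol synthesis genes (adjusted p = 5.8e-12) included the sterol enzymes MSMO1 (-1.84 ± 0.10) and DHCR7 (-1.45 ± 0.09) and the regulator SREBF2 (-1.13 ± 0.07) in the authors' deposited table. ATF4 stress genes fell in 18 of 20 and rose in 1 (median -1.06, adjusted p = 3.09e-20) and chaperones in 13 of 14 with 1 higher (-0.75, 9.73e-12), in the authors' deposited table. Ribosomal proteins fell in 28 of 30 (median -0.42, adjusted p = 3.12e-11) in the authors' deposited table. DDIT3 stood at -1.76 ± 0.07, HSPA5 at -1.17 ± 0.05 and RPL22 at -1.09 ± 0.07 in the authors' deposited table. G2/M genes had a median of 0.60 (adjusted p = 1.13e-19), with PLK1 at 1.11 ± 0.06, MKI67 at 1.10 ± 0.05 and HMMR at 1.40 ± 0.07 in the authors' deposited table. MAPK feedback genes rose in 17 of 20 and fell in 2 (adjusted p = 5.31e-10), with ETV4 at 2.40 ± 0.10, DUSP6 at 1.36 ± 0.07 and CCND1 at 1.66 ± 0.05 in the authors' deposited table. Matrix genes rose in 19 of 30 and fell in 6 (adjusted p = 1e-09) and TGF-beta targets in 10 of 15 with 2 lower (9.67e-11), in the authors' deposited table. YAP and TAZ targets rose in 12 of 24 and fell in 2 (adjusted p = 0.00122) in the authors' deposited table. TGFBI stood at 4.17 ± 0.11, CTGF at 3.95 ± 0.21 and COL5A1 at -1.58 ± 0.05 in the authors' deposited table. Replication histones rose in 10 of 13 (adjusted p = 3.09e-20) and imprinted genes in 14 of 22 with 3 lower (5.39e-06), with HIST1H1C at 4.61 ± 0.11 and PEG10 at 1.54 ± 0.05 in the authors' deposited table. Fibroblast markers were higher in 11 of 14 members with 1 lower (adjusted p = 2.29e-07), endothelial in 8 of 11 with 1 lower (0.0185, up to 0.0616) and epithelial in 10 of 14 (0.0456, up to 0.122), from the authors' deposited table. PAX3 (1.30 ± 0.08) rose and FGFR4 (-1.47 ± 0.07), MYC (-1.25 ± 0.07) and DES (-0.90 ± 0.09) fell in the authors' deposited table. When adjusted over the list alone, 20 matrix genes and 14 YAP and TAZ targets rose, 7 matrix genes, 4 imprinted genes and 2 fibroblast markers fell, and the other counts of this paragraph were the same. With the log2 fold change as the statistic, 12 lists passed, and the G2/M and MAPK feedback lists did not pass and pointed down. The matrix, TGF-beta, YAP and TAZ and cholesterol calls ended in that setting too. Of 42 lists 19 passed, 14 higher and 5 lower, and with an inter-gene correlation of 0.05 the contractile (adjusted p = 0.0683), NF-kB (0.0851), endothelial (0.0616), epithelial (0.122) and other dasatinib kinase (0.101, up to 0.225) calls were lost.

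**Figure D2:**
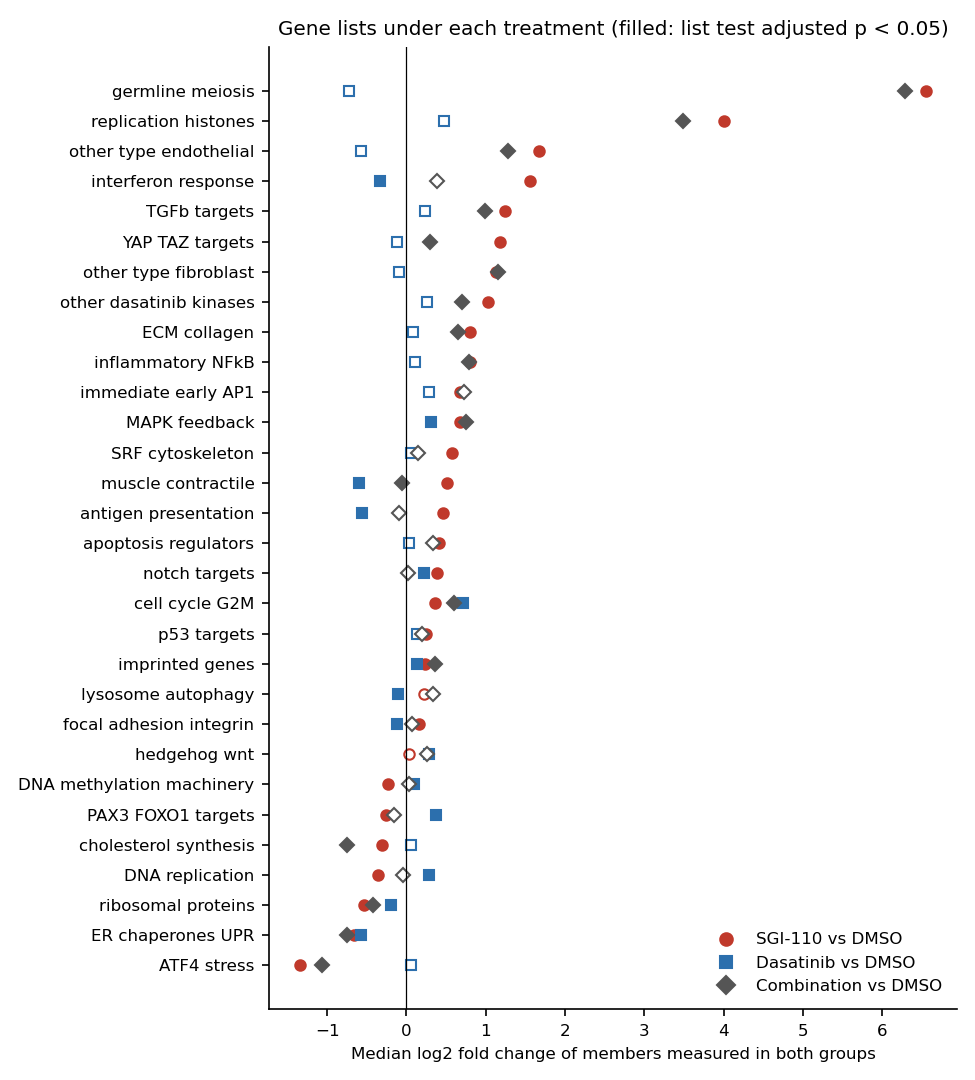
Median log2 fold change against DMSO (horizontal axis) of the members measured in both groups, for each gene list past the list test in at least 1 of the 3 treatments and with at least 5 such members; circles show SGI-110, squares dasatinib, diamonds the combination, and filled symbols a list test adjusted p under 0.05, computed from the authors' deposited table. Interferon genes stand at 1.56 with SGI-110, -0.34 with dasatinib and 0.38 with the combination.

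The comparison of the combination with SGI-110 asks what dasatinib added to SGI-110. Interferon-stimulated genes were lower with both drugs than with SGI-110 alone in 23 of 32 members and higher in none, in the authors' deposited table. Contractile genes (19 of 30), YAP and TAZ targets (17 of 24), matrix genes (19 of 30) and cholesterol synthesis genes (18 of 22) were lower as well in the authors' deposited table. DNA replication genes (22 of 30, with 1 lower) and mitotic genes (16 of 26) were higher in the authors' deposited table. In total 3237 genes were higher and 3860 lower out of 22743 with an adjusted p, and 337 were higher and 1115 lower by at least 1 log2, in the authors' deposited table. At a mean normalised count of at least 100 the balance turned, 2791 higher and 2607 lower.

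The mesenchymal transcription factor gene PRRX1 (chromosome 1, 170662728 to 170739419) rose 11.6-fold (3.54 ± 0.17) in the authors' deposited table. CAPN6 (3.28 ± 0.26), the R-spondin receptor gene LGR5 (2.96 ± 0.38), DCX (2.56 ± 0.16) and the deiodinase gene DIO2 (2.46 ± 0.11) rose in the authors' deposited table. PTP4A3 (-3.82 ± 0.44), the complement gene C1S (-3.09 ± 0.13), the muscle gene XIRP1 (-3.02 ± 0.15) and CPA4 (-2.63 ± 0.07) fell in the authors' deposited table.

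In the interferon list (median -0.69, limma adjusted p = 2.59e-17), ISG15 stood at -1.60 ± 0.09, IFIT1 at -2.00 ± 0.17, IFIT2 at -1.96 ± 0.13 and IFI44 at -1.12 ± 0.06 in the authors' deposited table. Antigen presentation genes were lower in 11 of 20 and higher in 1 (adjusted p = 7.79e-09), with TAP1 at -0.87 ± 0.08 in the authors' deposited table. Contractile genes had a median of -0.70 and 1 member higher (adjusted p = 2.36e-21), with MYL1 at -2.27 ± 0.12, TNNI1 at -1.73 ± 0.09 and TPM1 at -0.98 ± 0.06 in the authors' deposited table. In the YAP and TAZ list (adjusted p = 3.79e-23) CYR61 fell to 0.348-fold (-1.52 ± 0.06), and the receptor kinase gene AXL (-1.56 ± 0.09) and TGFB2 (-2.36 ± 0.17) fell in the authors' deposited table. Matrix genes (5 higher, adjusted p = 1.05e-16) included COL1A1 (-2.00 ± 0.06) and TIMP3 (-0.98 ± 0.06) in the authors' deposited table. SRF and cytoskeleton genes (12 of 22 lower, adjusted p = 4.66e-09) and focal adhesion genes (12 of 22 lower, 2 higher, 4.66e-09) included MYL9 (-1.82 ± 0.10) and ITGA3 (-2.09 ± 0.08) in the authors' deposited table. Cholesterol synthesis genes had a median of -0.47 (adjusted p = 4.56e-15), with INSIG1 at -2.04 ± 0.11 and MSMO1 at -1.44 ± 0.10 in the authors' deposited table. Cancer-testis genes were lower in 8 of 30 (adjusted p = 0.00296) and germline genes in 10 of 24 with 1 higher (0.0139, up to 0.0974) in the authors' deposited table. PRAME stood at -1.28 ± 0.06, TEX14 at -0.65 ± 0.09 and DAZL at -0.44 ± 0.08 in the authors' deposited table. Replication histones were lower in 8 of 13 (adjusted p = 2.32e-06), with HIST1H1C at -1.13 ± 0.07 in the authors' deposited table. With p adjusted over the list alone, 20 matrix, 13 SRF, 13 focal adhesion and 13 germline genes were lower and 1 interferon and 2 germline genes higher, with the other counts of this paragraph the same.

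AP-1 genes (11 of 20 lower, 3 higher, adjusted p = 5.82e-06), p53 targets (11 of 26 lower, 3 higher, 0.00143) and TGF-beta targets (7 of 15 lower, 3 higher, 0.000709, up to 0.151) were lower, from the authors' deposited table. Notch targets (8 of 15 lower, 1 higher, adjusted p = 0.00295) and epithelial markers (6 of 14 lower, 1 higher, 0.0161, up to 0.061) were lower too, from the authors' deposited table. JUN (-0.64 ± 0.07), PLK2 (-0.91 ± 0.05), CDKN1A (-0.60 ± 0.08) and CLDN4 (-1.78 ± 0.13) fell in the authors' deposited table. DNA replication genes had a median of 0.30 (adjusted p = 7.41e-14) and G2/M genes of 0.19 (5.72e-09), with MCM4 at 0.50 ± 0.04 and FOXM1 at 0.50 ± 0.05 in the authors' deposited table. PAX3-FOXO1 targets were higher in 8 of 19 and lower in 3 (adjusted p = 3.85e-06, up to 0.158), with ASS1 at 1.07 ± 0.07 and ALK at 1.47 ± 0.10 in the authors' deposited table. Ribosomal proteins were higher in 8 of 30 (adjusted p = 0.0056, up to 0.083), with RPSA at 0.30 ± 0.07, in the authors' deposited table. Adjusted over the list alone, 12 AP-1 genes, 13 p53 targets, 9 Notch targets, 7 epithelial markers and 5 PAX3-FOXO1 targets were lower, and 23 replication genes, 18 G2/M genes, 4 TGF-beta targets and 2 epithelial markers higher. Of 42 lists 20 passed, 4 higher and 16 lower, and with an inter-gene correlation of 0.05 the germline (adjusted p = 0.0813), epithelial (0.061) and ribosomal (0.061) calls were lost. With the log2 fold change as the statistic 3 lists passed.

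The next comparison asks whether dasatinib acted alike with and without SGI-110. It is the log2 change of the combination against SGI-110 minus that of dasatinib against DMSO, and 4321 of 29639 genes differed, 1804 upward and 2517 downward, computed from the authors' deposited table. Centred on the median gene, a shift of -0.04 log2, 2109 were upward and 2181 downward. Mitotic genes, which rose with dasatinib alone, rose less on top of SGI-110: 23 of 26 had a lower difference, and endoplasmic reticulum chaperones had a higher difference in 14 of 14, computed from the authors' deposited table. A lower difference was also found for 12 of 32 interferon genes (1 higher), 13 of 20 AP-1 genes (2 higher), 11 of 24 YAP and TAZ targets (1 higher) and 14 of 22 cholesterol genes, while the other members were not past the threshold, computed from the authors' deposited table.

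TXNIP had a difference of -3.65 ± 0.13, MYLK4 of -3.25 ± 0.31 and COX10, a mitochondrial heme enzyme gene (chromosome 17, 14069496 to 14208677), of 2.06 ± 0.10, computed from the authors' deposited table. G2/M genes had a median difference of -0.51 (limma, adjusted p = 2.21e-32), with KIF20A at -0.87 ± 0.07 and AURKA at -0.76 ± 0.09, computed from the authors' deposited table. Chaperones had a median difference of 0.67 (adjusted p = 4.53e-37), with HSPA5 at 1.43 ± 0.07, computed from the authors' deposited table. Ribosomal proteins had 21 of 30 upward and none downward (adjusted p = 2.84e-11), and cholesterol genes 14 of 22 downward (4.76e-15), with FDFT1 at -1.10 ± 0.10, computed from the authors' deposited table. AP-1 genes had 13 of 20 downward and 2 upward (adjusted p = 4.15e-10), with FOS at -2.29 ± 0.15, and Notch targets 9 of 15 downward and 1 upward (1.77e-07), with HES1 at -1.28 ± 0.18, computed from the authors' deposited table. Interferon genes had 12 of 32 downward and 1 upward (adjusted p = 1.16e-05), with IFI44 at -1.05 ± 0.09, computed from the authors' deposited table. YAP and TAZ targets had 11 of 24 downward and 1 upward (adjusted p = 1.16e-09), with CYR61 at -1.54 ± 0.09 and CTGF at -1.71 ± 0.25, computed from the authors' deposited table. Matrix genes (12 of 30 downward, 2 upward, adjusted p = 4.17e-08), p53 targets (11 of 26 downward, 1.34e-05) and histones (8 of 13 downward, 1.5e-07) went the same way, computed from the authors' deposited table. COL1A1 stood at -1.71 ± 0.10, DDB2 at -1.18 ± 0.15 and HIST1H1C at -1.60 ± 0.14, computed from the authors' deposited table. Contractile genes had 8 of 30 upward and 7 downward, and their list was not past the threshold (adjusted p = 0.91), nor was antigen presentation (4 of 20 upward, 2 downward, 0.107), computed from the authors' deposited table. Once adjusted over the list alone, 26 ribosomal and 3 matrix genes were upward and 16 cholesterol, 10 Notch, 13 interferon, 13 YAP and TAZ, 14 matrix, 9 histone and 9 contractile genes downward, with the other counts the same. Of 42 lists 19 passed, 4 upward and 15 downward. In at least 1 of the 4 settings named for the list tests 5 calls ended: ATF4 stress (adjusted p up to 0.242), MAPK feedback (0.156), SRC family and ABL (0.0728), hedgehog and Wnt (0.105) and NF-kB (0.118). Of the remaining calls, only that of histones also passed with the log2 fold change as the statistic.

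The combination against dasatinib asks what SGI-110 added to dasatinib. The values were computed from the authors' deposited table, and 7895 genes were higher and 4904 lower. At a mean normalised count of at least 100 the balance turned, 3360 higher and 4276 lower. Germline genes (24 of 24) and cancer-testis genes (27 of 30) were higher, and interferon genes were higher in 23 of 32 members and lower in 2 (limma, adjusted p = 0.00164), computed from the authors' deposited table. CCND1 (2.05 ± 0.06), CTGF (3.06 ± 0.15), HLA-B (1.13 ± 0.08) and ISG15 (1.18 ± 0.11) rose, computed from the authors' deposited table. KCNT1 (-3.39 ± 0.20), the asparagine synthetase gene ASNS (-2.85 ± 0.16), SORCS2 (-2.85 ± 0.09) and the cystine transporter gene SLC7A11 (-2.66 ± 0.21) fell, computed from the authors' deposited table. Lysosome and autophagy genes were higher in 14 of 20 and lower in 1 (adjusted p = 5.03e-06), computed from the authors' deposited table. Other lists were lower: ATF4 stress genes in 16 of 20 with 2 higher (adjusted p = 6.91e-20), cholesterol synthesis in 18 of 22 with 3 higher (4.47e-17), DNA replication in 23 of 30 with 2 higher (4.46e-08), PAX3-FOXO1 targets in 13 of 19 with 4 higher (1.55e-07) and ribosomal proteins in 20 of 30 with 1 higher (1.26e-05), computed from the authors' deposited table. Markers of other cell types were higher, fibroblast in 11 of 14 with 1 lower (adjusted p = 5.75e-10) and epithelial in 11 of 14 (0.00491), computed from the authors' deposited table. For the lists of this paragraph the counts adjusted over the list alone were the same, except 23 ribosomal genes lower. Of 42 lists 23 passed, 17 higher and 6 lower. In at least 1 of the 4 settings named for the list tests 7 calls ended: DNA methylation machinery (adjusted p up to 0.108), MAPK feedback (0.169), imprinted genes (0.0981), NF-kB (0.126), other dasatinib kinases (0.173), endothelial (0.0737) and neural markers (0.125). With the log2 fold change as the statistic, the interferon, antigen presentation, matrix, TGF-beta and YAP and TAZ calls ended too. So did the PAX3-FOXO1, cholesterol and lysosome calls, and the lysosome list then pointed down.

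**Figure D3:**
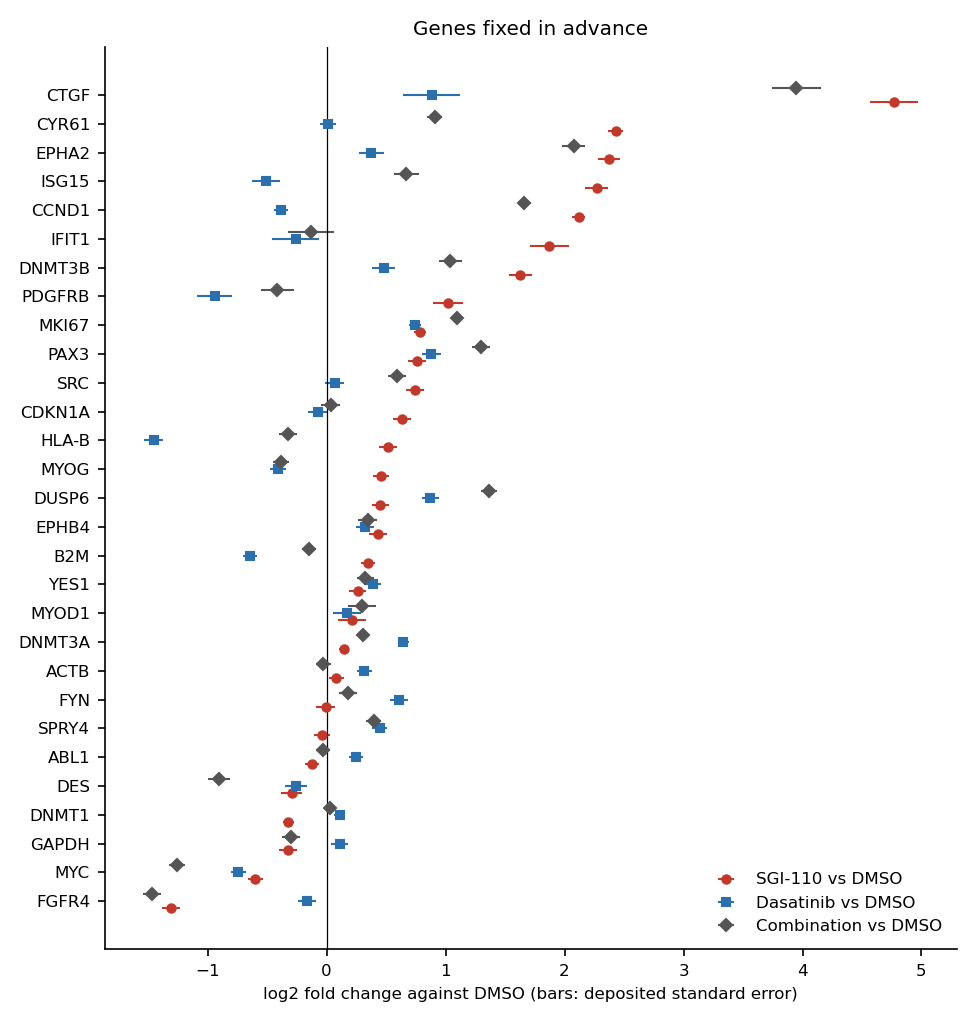
Log2 fold change against DMSO (horizontal axis, bars the deposited standard error) of the genes fixed in advance that had a measurable level in DMSO, for SGI-110 (circles), dasatinib (squares) and the combination (diamonds), from the authors' deposited table. CTGF stands at 4.77, 0.88 and 3.95 and FGFR4 at -1.31, -0.16 and -1.47.

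Of the genes past the threshold against DMSO, 6734 rose and 3598 fell with both SGI-110 and the combination and 281 went opposite ways, in the authors' deposited table. Independent calls would give 2586 and 857. For SGI-110 and dasatinib 1626 rose and 1258 fell with both and 1460 went opposite ways, where independent calls would give 1324 and 637, from the authors' deposited table. Each pair shares its DMSO libraries: over 11523 genes the covariance of the log2 changes was 0.91 for SGI-110 and the combination and 0.0538 for SGI-110 and dasatinib, where shared controls alone gave 0.0102 and 0.0103. Of the 8671 genes that rose with SGI-110, 2417 were lower and 849 higher in the combination than with SGI-110 alone, and of the 4866 that fell, 623 were lower and 1362 higher, in the authors' deposited table. Both comparisons use the SGI-110 libraries, so noise alone parts these genes: in simulated draws where dasatinib added nothing, a mean of 76.3 of 8059 risen genes were lower and 46.9 higher, and of 4585 fallen genes 24.2 were lower and 53.2 higher.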

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

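The tests of the scaling of the libraries, of the simple sum of the drug effects and of the standard errors were chosen after the results were seen. Whether dasatinib acted differently with and without SGI-110 was tested for every gene, and 4321 genes differed, computed from the authors' deposited table. The values below are these differences on the log2 scale.

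Among genes with a mean normalised count of at least 100, the largest upward differences of genes measured in all treatments were those of KLHDC7B (2.92), CHRNE (2.79), GP6 (2.79), SCN9A (2.39), BEST1 (2.35) and COX10 (2.06), computed from the authors' deposited table. The largest downward differences of such genes were those of DNAH3 (-4.65), TXNIP (-3.65), MYLK4 (-3.25), ART3 (-3.08) and SORL1 (-2.94), computed from the authors' deposited table. DNAH3 had a large standard error for SGI-110 against DMSO, as given above. Its DMSO level may lie close to the limit of measurement, so the size of its difference is uncertain. EPB41L3 and FAM9C (upward, adjusted p = 0.034 and 0.0176) and COL26A1, EMILIN3 and SSX1 (downward, 0.00487, 0.0285 and 0.0369) also differed, and no size is given because they had no measurable level in at least 1 treatment, computed from the authors' deposited table. Of the genes fixed in advance, methyltransferase and kinase genes differed: DNMT1 (0.24), DNMT3A (-0.49), DNMT3B (-1.07), YES1 (-0.32), FYN (-0.42), EPHA2 (-0.67) and EPHB4 (-0.41), computed from the authors' deposited table. Muscle and growth genes differed as well: MYOG (-0.44), DES (-0.35), PAX3 (-0.34), CDKN1A (-0.53) and MKI67 (-0.43), computed from the authors' deposited table. Interferon, antigen presentation and YAP target genes completed the set: ISG15 (-1.09), IFIT1 (-1.75), HLA-B (0.61), CTGF (-1.71) and CYR61 (-1.54), with ACTB at -0.42, computed from the authors' deposited table.

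The lower level of interferon genes in the combination than with SGI-110 was weighed against 3 plain explanations. A weaker SGI-110 effect on all induced genes alike was tested on 27 of 32 members. These had a measurable level in DMSO and passed a minimum mean count, and the other members were left out. The median of the 27 was -0.61, below all but 0.04% of 10000 random lists matched on SGI-110 effect and level (median -0.17, 95% from -0.40 to 0.04). A plain sum of the separate drug effects would leave no interaction, yet the median interaction of the 26 members measured in all treatments was -0.57. The list test adjusted p was 1.16e-05 (limma), and up to 0.00597 in the other list settings but the log2 fold change. With the log2 fold change as the statistic the list did not pass. These 2 explanations are argued against as the whole cause, the plain sum with the limit just given. The scaling of the libraries stays open: the median gene with a count of at least 100 stood at 0.0176, but size factors set that median near 0 whatever the true scaling. A factor common to all genes would leave the gap between the list and its matched lists as it is, so what stays open is whether the amount of these transcripts fell or that of other genes rose. A combined action of the drugs on these genes was not tested further, and the correlation between the genes was not estimated.

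The fall of ribosomal protein genes with SGI-110 was weighed against transcript length and scaling. Their median of -0.54 lay below all but 0.13% of 10000 random lists matched on exonic length and level (median -0.20, 95% from -0.42 to -0.000416). Length is argued against as the whole cause, but the matched lists also lay below 0, so length and level may account for part of the fall. How close the matched genes came in length and level is not given. The correlation between ribosomal protein genes was not estimated, so the 0.13% may overstate the evidence. Scaling stays open, since the median gene with a count of at least 100 (-0.0233) is set near 0 by the size factors. Differences in depth or RNA quality between libraries could not be examined, and a response of the cells to SGI-110 stays open.

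The deposited standard errors were weighed for the number of libraries behind each comparison. The lowest standard error of dasatinib against DMSO among genes with a mean count of at least 100 and no measurable level in either group was 1.67, against 1.18 predicted for 6 libraries and 1.67 for 3. These genes were chosen by a group standard error of at least 1.17 log2, a limit set for 3 libraries. A value near 1.18 could therefore not appear, and that check decides nothing. The largest standard error, 6.01, was not chosen this way. It lies above the 4.25 predicted for 6 libraries at the highest dispersion taken for a fit of 24 libraries. A lower dispersion of 12 predicts less, 3.12. If that highest dispersion and the lower limit of 0.5 counts per library hold, this argues against both cell lines joined. It matches 3 libraries of 1 line in a fit of 24 libraries (6.01 predicted). Which line it was cannot be told apart from these tables: the share of the mean level recovered for the contrasted libraries had a median of 1.65 for PAX3-FOXO1 targets, above random lists (1.14, 95% from 0.685 to 1.58), but only 8 of 19 members have a value, 42.1%, which makes that check void.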

How the results depend on the processing

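All alternatives were planned except leaving out genes with an unmeasurable group, which was chosen after seeing the data. No paired analysis was possible because the tables used here hold no value per library. For the same reason a replicate block, leaving out each replicate, each cell line alone, other size factors or count tools, other splits of the samples and an estimated inter-gene correlation were not run, and the cell line difference was not computed. The part of chance in how the samples fall into groups could not be examined. Depth limits are unknown.

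With a log2 change of at least 1, counts fell to 6461 (SGI-110), 1021 (dasatinib), 6133 (combination), 1452 (combination against SGI-110), 812 (interaction) and 5869 (combination against dasatinib). With Bonferroni they were 6692, 2219, 6390, 2429, 1247 and 6023. Both remove genes by construction. With the log2 fold change as the list statistic, 15, 1, 12 and 3 lists passed for the 4 deposited comparisons in that order. Calls of the interaction and of the combination against dasatinib ended in this setting too, as given with those comparisons. The cause was not tested. The overlap of SGI-110 and the combination was 6806 genes at a mean count of at least 50 and 4915 at a log2 change of at least 1, and that of SGI-110 and dasatinib 357 at a log2 change of at least 1, with fewer genes tested or called by construction.

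Other settings, an adjusted p under 0.01 and adjustment over every gene among them, kept the total counts of genes and lists within 1.5 times. At a mean count of at least 50, 9122, 5905, 9189, 6195, 4695 and 8857 genes passed in the same order. The counts of higher genes moved more: 4606 for SGI-110 (8671 before), 4802 for the combination (8326) and 4151 for the combination against dasatinib (7895), where 4706 were then lower. Without genes that had an unmeasurable group, 10602, 6277, 10613, 6481, 4288 and 10084 passed, of which 5756 were higher for SGI-110 (54.3%, 64.1% before), 5737 for the combination (54.1%, 62.9% before) and 5198 for the combination against dasatinib (51.5%, 61.7% before). Lists past the threshold were 25, 12, 14 and 17 at a correlation of 0.05, 32, 12, 21 and 23 on ranks, 24, 10, 16 and 17 at a mean count of at least 50, and 27, 14, 16 and 21 without unmeasurable genes. No list passed in the opposite direction in any list setting, the log2 fold change included. In 1 setting the direction turned without passing for MAPK feedback, G2/M, p53, Notch, apoptosis and focal adhesion lists with SGI-110. The same held for focal adhesion with dasatinib and for MAPK feedback and G2/M with the combination. In the combination against dasatinib it held for MAPK feedback and lysosome genes. Centring on the median gene left 123 of 128 values of the fixed genes with their direction and call. FYN with SGI-110 (0.0145) and CYR61 with dasatinib (-0.0387) turned sign, with neither past the threshold before or after. FGFR4 passed with dasatinib (-0.21) and in the combination against SGI-110 (-0.18), and FYN did not pass in the latter (0.17). With dasatinib, centring moved the share of genes that rose from 57.4% to 47.0%, and for the interaction from 41.7% to 49.2%. The shift itself caused these changes.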

Other observations

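Beyond the lists, the kinds of gene that rose with SGI-110 differed in share. Of 16302 protein-coding genes 6484 rose (39.8%), of 794 long intergenic RNAs 243 (30.6%), of 725 antisense RNAs 160 (22.1%) and of 1484 processed pseudogenes 156 (10.5%), in the authors' deposited table. Differences in level between these kinds were not taken out.

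Dasatinib alone and dasatinib on top of SGI-110 share no libraries, and 1410 genes rose and 1076 fell in both, with 674 in opposite directions, in the authors' deposited table. Independent calls would give 572 and 501. Across 11523 genes, which are not independent replicates, Pearson's r of the log2 changes was 0.418 and Spearman's rho 0.309.

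Of the 4939 genes with a recovered level share, 1853 had a mean count of at least 100 and 1 annotated place on the autosomes, chromosome X or the mitochondrial genome. Among the 100 highest of these, 16 lay on chromosome 12, which holds 109 of the 1853, so that 5.88 would be expected. This was seen after the values were examined. With equal numbers of libraries from each line a share cannot exceed 2, yet only 91.3% of the 4939 shares were at or under 2. Some of the highest shares may therefore be errors of the estimate. Rh30 as the contrasted line is a hypothesis only: its test on PAX3-FOXO1 targets (median share 1.65) is void for the reason given above, and no line is assigned here.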
